A study of Casuarina glauca with 4 samples.

How the data were processed

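Gene expression was measured in root nodules of the actinorhizal tree Casuarina glauca, formed with the nitrogen-fixing actinobacterium Frankia. Nodules were collected at day 21 from untreated plants and from plants given 25 µM 1-naphthoxyacetic acid (1-NOA), a blocker of auxin uptake into cells. Each of the 4 samples was hybridised to its own single-colour (Cy3) Agilent array of custom design. The labels give 2 control arrays and 2 1-NOA arrays, numbered replicates 2 and 3 in both groups. They do not say whether the samples came from separate sets of plants.

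Spot intensity was deposited as scanner output for each array. Per the file headers, the intensity values came from Agilent Feature Extraction 10.1.1.1, while the submitters' processing notes name version 9.1. Per the file headers, the processed intensity had its background subtracted, with spatial detrending, multiplicative detrending and surrogate values for dim spots, and was not scaled between arrays. The authors also deposited a table of log2 values for the same arrays, with their scale and centring unstated. Differences between arrays in that table matched those of the log2 processed intensity once scaled as for the main test below. The remaining shift between arrays was at most 0.05 (log2). The column medians of the table were -0.10 and 0.00 for control replicates 2 and 3, and 0.00 and 0.00 for 1-NOA replicates 2 and 3. Each probe had been centred, and the arrays behind that centring stay unknown.

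For the main test, the log2 of the processed intensity was reduced by each array's 75th percentile over non-control probes. Spots with a non-uniformity or population outlier mark were set to missing. Probes were kept when well above background on at least 2 arrays and unmarked on at least 3. The groups were compared with limma 3.58.1 in R 4.3.3, by a linear model with group only and empirical Bayes moderation, two-sided. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Intervals are 95% intervals from the same model. A probe not well above background on any array of a group was given as at least N-fold. That bound set the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. It carries no sampling error.

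The signal over background limits precision, as does the number of arrays. Probes well above background numbered 9633 and 9109 on control replicates 2 and 3, and 8840 and 8847 on 1-NOA replicates 2 and 3, out of 14543. Spots marked as outliers numbered 108, 128, 164 and 71 in the same order, and 0 spots were saturated. All arrays were on 1 slide, read in 1 scan, so neither could be fitted as a batch. Control arrays lay in slide row 1 and 1-NOA arrays in slide row 2, so slide row and group cannot be told apart.

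The model was tested on simulated data, with 200 of 9373 probes changed in the 1-NOA against control comparison. With the spread of the real arrays, it called 0 of 50 probes changed by 1 on the log2 scale, 18 of 50 changed by 2, 22 of 50 changed by 3 and 39 of 50 changed by 5. There were 6 false calls. With an SD of 0.05 it called 50 of 50 at each size, with 7 false calls. The simulated noise was independent between probes and held no effect of array position, so these false calls do not cover such an effect.

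Before the data were examined, 26 gene lists and a rule for named genes were fixed. The lists covered auxin, symbiosis signalling, haemoglobin, proteases, nitrogen, sucrose, flavonoids, lignin, suberin, cell wall, defence, oxidative stress, detoxification, other hormones, cell cycle, tissue markers, transport, metals, chaperones, ribosomal proteins and transcription factors. They were to be matched on gene descriptions and tested with camera where at least 5 probes were measured. All 14543 non-control probes carry the description Unknown and no position in a genome. Symbiosis signalling matched 1 probe, the other 25 lists matched 0, and 0 lists could be tested. The rule named genes by description, by list and, whatever their values, the auxin influx carriers, SYMRK, NIN, CCaMK, haemoglobin, Cg12 and glutamine synthetase. For probes without gene names, it allowed at most 2 probe IDs that rose and 2 that fell. Gene symbols stand in 4 probe names, of which SYMRK and DMI3 (another name of CCaMK) fall under the rule.

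Alternatives covered background correction with normexp (offset 50), normalization, filters, outlier marks, the replicate block, the variance prior, array weights, the deposited log2 table, thresholds and leaving out each array. Alternatives based on array position and on spike-in transcripts were added after seeing the data. Permutation tests and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.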

Results

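Transcript levels in Casuarina glauca nodules were recorded on arrays of 14543 probes, each of 60 bases, which hold 14488 distinct sequences. Casuarina is a tree whose roots form nitrogen-fixing nodules with the soil actinobacterium Frankia. Control nodules (n = 2) and nodules of plants treated with 25 µM 1-NOA (n = 2) were sampled at day 21. The 75th percentile of the processed intensity was 2233 and 2056 on control replicates 2 and 3, and 1993 and 1763 on 1-NOA replicates 2 and 3. Between 60.8% and 66.2% of probes were well above background on an array. P-values and intervals given here measure only the spread between these samples, which may be technical.

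The comparison of treated with control nodules addressed which nodule transcripts differ with 1-NOA. It cannot by itself tie a difference to auxin influx. CG-SymRK, the probe for the symbiosis receptor-like kinase needed for nodule formation, was bright in both groups. Its log2 signal relative to the 75th percentile was 2.65 ± 0.06 in control nodules and 2.42 ± 0.15 in 1-NOA nodules (SD, n = 2 each). The log2 difference was -0.22 (SE 0.19, 95% interval -0.76 to 0.32, limma adjusted p = 0.666). CgDMI3, the probe for the calcium- and calmodulin-dependent kinase of the same signalling pathway, measured -0.88 ± 0.23 in control and -0.98 ± 0.19 in 1-NOA nodules. Its log2 difference was -0.10 (SE 0.23, 95% interval -0.75 to 0.56, limma adjusted p = 0.872). Neither kinase probe passed the test. On this scaling both intervals leave out a 2-fold difference, but they cover only the spread between these arrays. Because slide row and group cannot be told apart, they do not exclude a 2-fold response to 1-NOA. The sign of both differences turned with normexp and quantile normalization, to 0.11 for CG-SymRK and 0.17 for CgDMI3. With local correction for array position it turned too, to 0.08 for CG-SymRK and 0.10 for CgDMI3.

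A pair of probes that carry a gene symbol in their names were chosen after their values were seen. CL747Contig1(CgFNR) measured 0.98 ± 0.05 in control and 1.30 ± 0.06 in 1-NOA nodules, a log2 difference of 0.32 (SE 0.18, 95% interval -0.18 to 0.82, limma adjusted p = 0.629). With normexp and quantile normalization its log2 difference was 1.25, also short of the threshold, and with local correction 0.02. It lies in array row 6 and column 52, and a probe of identical sequence in row 79 gave -0.14. CL40Contig1(CgFdx) measured 0.13 ± 0.21 and 1.12 ± 0.75, a log2 difference of 0.99 (SE 0.44, 95% interval -0.25 to 2.22, limma adjusted p = 0.592). The 1-NOA arrays differed for this probe, at 1.64 and 0.59. It lies in array row 174 and column 3, and its log2 difference was -0.68 with normexp and quantile normalization. Neither probe passed the test.

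**Figure D1:**
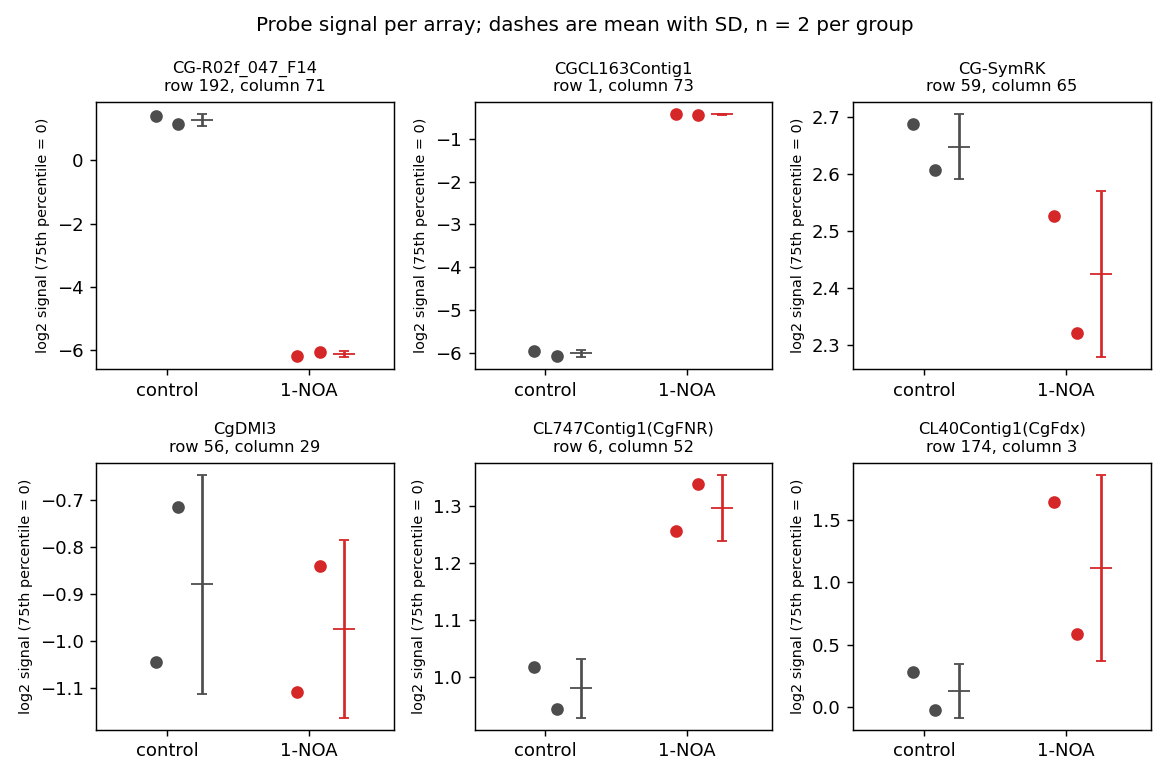
Log2 signal relative to the 75th percentile (y axis) on each control and 1-NOA array (x axis) for 6 probes, with the mean and SD of 2 arrays per group as dashes and bars. The y axes differ between panels: CG-R02f_047_F14 is at least 107-fold higher in control and CGCL163Contig1 at least 44.3-fold higher in 1-NOA nodules on this scaling, the dimmer group being not well above background, and the 4 probes with gene symbols differ by -0.22 to 0.99 (log2). The at-least bounds carry no sampling error.

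Of 9302 probes tested, 2 passed an adjusted p of 0.05 with limma, 1 higher and 1 lower in 1-NOA nodules. At an unadjusted p under 0.05 there were 847, of which 394 were higher and 453 lower. Leaving out single arrays gave 585 of 848 higher without control replicate 2, 533 of 714 without control replicate 3, 245 of 797 without 1-NOA replicate 2 and 479 of 1173 without 1-NOA replicate 3. It was also 1808 of 2182 without the background filter and 202 of 606 with spike-in scaling. CGCL163Contig1, in array row 1 and column 73, rose from -6.00 ± 0.08 in control to -0.44 ± 0.01 in 1-NOA nodules (SD, n = 2 each). It was not well above background on either control array, so the rise on this scaling was at least 44.3-fold (limma adjusted p = 0.0483). Other settings fitted less than that bound, at a log2 difference against the background-level control signal of 4.09 with normexp and quantile normalization and 4.22 with local correction for array position, where it no longer passed the test (limma adjusted p = 0.0958). Its sequence is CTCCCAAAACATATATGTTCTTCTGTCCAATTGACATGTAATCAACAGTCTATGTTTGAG. CG-R02f_047_F14, in array row 192 and column 71, fell from 1.27 ± 0.19 to -6.13 ± 0.09. It was not well above background on either 1-NOA array, so the control signal on this scaling was at least 107-fold higher (limma adjusted p = 0.0483). The same other settings also fitted less than that bound, with log2 differences against background-level 1-NOA signal of -6.10 and -5.87, the latter no longer past the test (limma adjusted p = 0.0766). Each of these probes passed in 7 of 17 other settings, with adjusted p from 0.0156 to 0.226 for CG-R02f_047_F14 and 0.0186 to 0.226 for CGCL163Contig1 (limma). Those 7 include saturated spots set to missing, which repeats the main test because 0 spots were saturated. They also include the deposited log2 table, whose differences between arrays matched the main values. The sequence of CG-R02f_047_F14 is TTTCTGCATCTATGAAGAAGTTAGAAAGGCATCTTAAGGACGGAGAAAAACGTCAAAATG. The files give no gene name or genome position for either.

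Both probes lie in an outermost row of an array of 192 rows and 82 columns. The median log2 difference over tested probes was 3.54 in row 1 (45 probes) and 2.70 in row 2 (47 probes). It was -2.61 in row 191 and -3.90 in row 192 (45 probes each). In rows 51 to 100 it was -0.06 over 2445 probes. Other inner rows departed further from 0, at -0.24 in rows 21 to 50 (1406 probes) and 0.23 in rows 143 to 172 (1485 probes). Differences of over 4-fold made up 19.1% of the 1451 tested probes within 5 rows or columns of a side, and 2.28% of the other 7851. Of the 52 probes at an adjusted p under 0.1 with limma, 50 lay in that outer zone. Without the outer 5 rows and columns, a choice made after seeing the data, limma called 0 probes at an adjusted p of 0.05 (smallest adjusted p = 0.643). There 584 of the 7851 probes, or 7.44%, had an unadjusted p under 0.05. The same restriction with normexp and quantile normalization also called 0, with 1239 at an unadjusted p under 0.05.

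**Figure D2:**
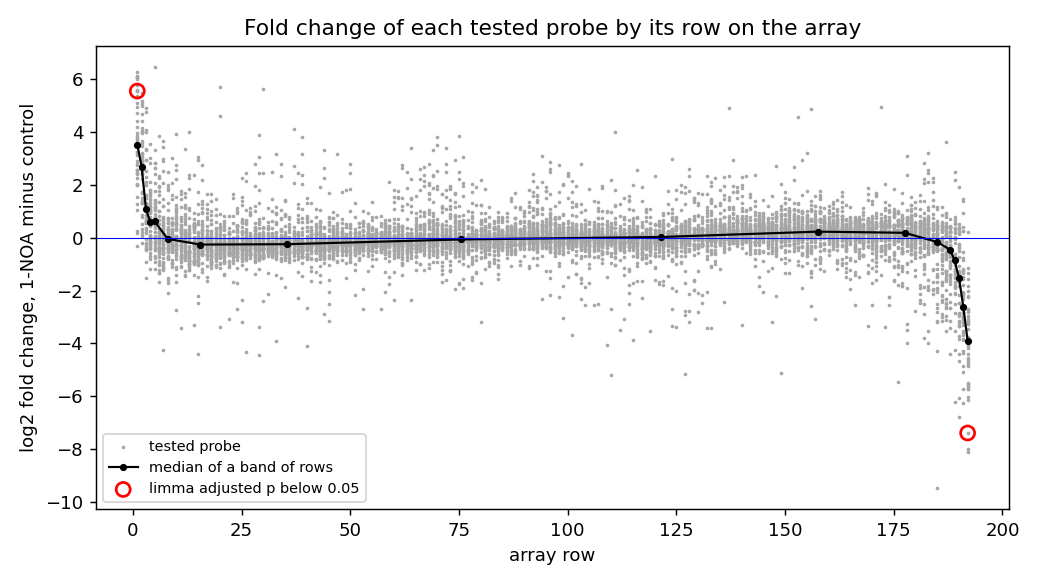
Log2 difference of 1-NOA minus control (y axis) for each of the 9302 tested probes against its array row (x axis), with medians of bands of rows as a black line and the 2 probes past the test ringed in red. The medians reach 3.54 in row 1 and -3.90 in row 192.

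**Figure D3:**
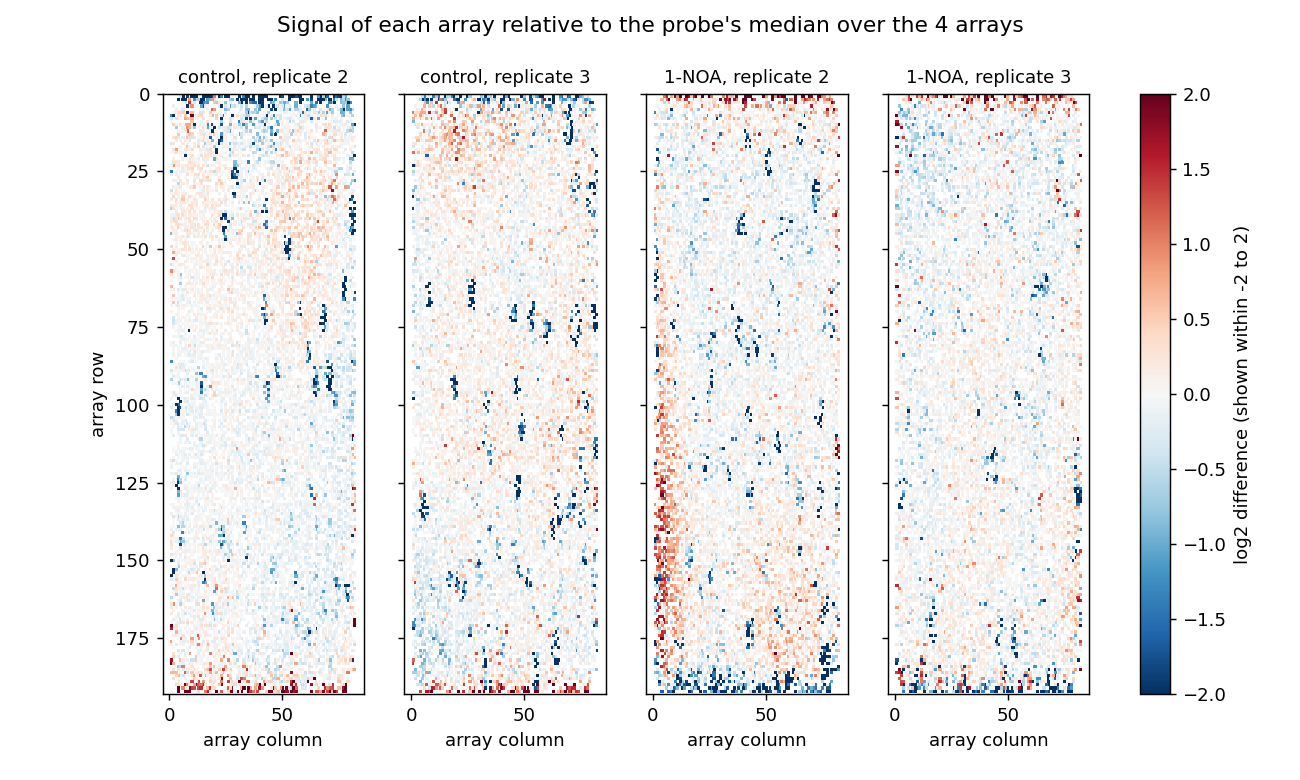
Position of tested probes (column on the x axis, row on the y axis) on each of the 4 arrays, coloured by the log2 difference from the probe's median over the 4 arrays, limited to -2 to 2 for display. Control arrays are low in the first rows and 1-NOA arrays in the last rows, and small patches of low signal lie on every array.

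Among the 7851 inner probes, the median absolute log2 difference was 0.24 between the control arrays and 0.26 between the 1-NOA arrays. Between groups it was 0.27 to 0.33. Pearson's r across these probes, which are not independent replicates, was 0.948 between the control arrays and 0.941 between the 1-NOA arrays. Between groups it was 0.964 for control replicate 2 with 1-NOA replicate 3, 0.946 for control replicate 3 with 1-NOA replicate 3, 0.934 for control replicate 2 with 1-NOA replicate 2 and 0.916 for control replicate 3 with 1-NOA replicate 2.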

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

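The settings based on array position or spike-ins were chosen after seeing the data. Setting saturated spots to missing could change nothing, with 0 spots saturated. The count of 2 changed probes was the same with a 2-fold minimum, and was 3 with array weights and with the deposited log2 table. It was 233 with normexp and quantile normalization, of which 195 lay within 5 rows or columns of a side, and 0 with the same setting restricted to the inner array. It was 6 with cyclic loess, 11 with the percentile over probes detected on all 4 arrays, and 25 with spike-in scaling, which moved the median of all probes to -0.19. It was 52 at an adjusted p of 0.1 and 0 at 0.01. It was 0 with quantile normalization, without the background filter, with detection on all 4 arrays, with outlier spots kept, and with the trended robust prior. It was also 0 without the outer 5 or 10 rows and columns and with local correction. Leaving out an array gave 0 to 0, a lone array being assumed to vary like the other group. Except where a setting removed those probes, the cause was not tested. The replicate block gave 0, and same-numbered arrays did not deviate together (r = -0.02). CGCL163Contig1 and CG-R02f_047_F14 kept their direction in the 17 settings that held them and passed the test in 7, saturated spots missing among them. The 4 probes with gene symbols passed in 0 settings. CG-SymRK changed sign in 3 of 21 settings and CgDMI3 in 5 of 21. Settings that alter only filters, the variance prior, array weights or the replicate block kept their log2 differences and could not turn a sign. A slide or scan block was not run, with 1 slide and 1 scan, nor were the list settings, with 0 lists tested. Signal over background limits dim probes.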

Other observations

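The limma test of single probes was planned and that of probe brightness was set before its result was seen; the other tests in this part were chosen after the result was seen. Away from the array sides, a pair of probes at different positions with an identical sequence had higher means in 1-NOA nodules, without passing the test. Among such pairs it was picked because the smaller of its changes was the largest, so the size of its changes is no independent support. CG-J02f_002_O09, in row 156 and column 16, measured -7.96 ± 0.96 in control and -3.06 ± 0.88 in 1-NOA nodules (SD, n = 2 each), and was not well above background on either control array. On this scaling the 1-NOA signal was at least 9.39-fold higher (limma adjusted p = 0.195), with bounds of 6.09-fold without 1-NOA replicate 2 to 14.5-fold without 1-NOA replicate 3 when single arrays were left out. The second copy, in row 76 and column 9, was also not well above background on either control array. On this scaling its 1-NOA signal was at least 4.20-fold higher, with bounds of 2.59-fold without 1-NOA replicate 3 to 6.82-fold without 1-NOA replicate 2, and its fitted 95% interval of -0.34 to 6.43 (log2) held 0 (limma adjusted p = 0.580). With normexp and quantile normalization the fitted log2 differences, which are no bounds, were 1.49 and 0.81, each smaller than the bound above. The shared sequence is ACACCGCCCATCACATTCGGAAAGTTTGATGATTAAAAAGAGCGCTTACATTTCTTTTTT, with no gene name or genome position in the files.

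Most probe names fall into 9 classes by their prefix, whose meaning the labels do not give, and names outside these classes were left out. Over inner probes the class medians of the log2 difference lay between -0.06 (R02, 2170 probes) and 0.08 (J07, 99 probes). For J07, 57 probes were higher and 42 lower in 1-NOA nodules, and 0 passed the test. Camera gave it an adjusted p of 0.357 over the 9 classes, and 0.807 with an estimated correlation. Among 12119 inner probes, 193 were well above background on both control arrays and neither 1-NOA array, and 15 the other way round. Their median log2 differences were -0.37 and 1.89, over sets that the detection limit itself selects. Negative-control spots had a median processed intensity of 5.74 and 9.06 on control replicates 2 and 3. On 1-NOA replicates 2 and 3 it was 12.2 and 10.8. The counts alone therefore do not show a difference in transcripts. Other splits of the arrays were lopsided too, at 41 against 2 for replicate 2 against replicate 3 and 25 against 3 for the crossed split.

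The changes in the outermost rows may come from signal lost at opposite ends of the arrays. Against their own inner medians, control replicates 2 and 3 lay at -3.86 and -2.49 in rows 1 and 2, and the 1-NOA arrays at 1.06 and 1.19. In the last 2 rows the 1-NOA arrays lay at -2.77 and -2.78 and the control arrays at 0.34 and 0.21. A response to 1-NOA as the only cause is argued against by the control arrays themselves, which averaged -3.18 in rows 1 and 2 (permutation p = 0.0001, the smallest that 10000 permutations can give). The lowest random set of as many inner probes came close, at -3.06. The permutation also takes probes as laid out without regard to their signal, which is not known. Copies of a sequence, tested first, settle less: in 6 of 8 pairs the outer copy lay further in the direction of its rows (one-sided exact sign test p = 0.145). Spots of spike-in transcripts went the same way, with apparent log2 differences of 1.38 in row 2 and -2.61 in row 191. They were few, and inner spike-in spots, with an SD of 0.58, reached an absolute difference of 3.14.

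Spots low on a single array, by over 2 on the log2 scale below the other 3, numbered 108 and 185 on control replicates 2 and 3, and 208 and 75 on 1-NOA replicates 2 and 3. They may mark small areas of lost signal: 82.8% of the 413 inner ones had another low spot of that array within 2 rows and columns, against 19.8% with positions permuted (permutation p = 0.0001, the smallest that 10000 permutations can give). Spots were counted only for probes well above background on the other 3 arrays, and brightness was ranked among those probes. Within that ranking the low spots were not confined to the dimmest, with a median brightness percentile of 46.0 (bootstrap 95% interval 42.3 to 49.9, spots taken as independent). This does not decide whether noise of dim probes contributed. The background filter, and lying that far below the other 3 arrays, both select against probes dim on all arrays. What removed the signal stays open.

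Inner probes separated the groups more often than the other splits of the 4 arrays. Groups did not overlap for 44.4% of 7663 inner probes, where chance gives 33.3%, and for 26.2% and 29.4% in the other splits, which are too few for a test and share out the same probes. A smooth gradient as the whole cause is argued against by local correction: among 6307 probes at least 10 spots from a side, those apart by over 0.5 (log2) numbered 238 against 72 and 94 before it and 172 against 63 and 73 after it, 2.36 times the higher other split (exact 95% interval 1.78 to 3.14, counting error only, with probes taken as independent). A difference in the labelled RNA or its hybridization may contribute. Inner copies of a sequence shared their difference over 27 pairs (Pearson's r = 0.807, permutation p = 0.00018). Spearman's rho was 0.480 (permutation p = 0.00309), and r was 0.372 without the 2 farthest pairs (permutation p = 0.0222). Each sequence gave 1 pair, its copies in the lowest rows, of 33 inner pairs in all. Pairs left out ran both ways, as CGCL1Contig2 at -0.06 against CGCL1Contig4 at 1.38, and CG-J04f_002_D12 at -0.82 against CG-R02f_034_J21 at -0.86. These differences were not locally corrected and the permutation ignored rows. A position effect shared by copies in nearby rows could therefore also raise the correlation. The position of the arrays on the slide cannot be told apart from 1-NOA, because 0 slide rows held both groups, and 1-NOA itself stays open.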
